A study of Homo sapiens with 2 samples.

How the data were processed

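Reh cells were transduced with 200 ng of virus for HA-tagged or untagged ETV6 in the presence of 8 µg/mL polybrene and kept in culture for 2 weeks, per the labels' protocols. Both lines were put through a pulldown with anti-HA beads, and the DNA was sequenced. The series design speaks of triplicates, while the sample titles name pools. The 2 samples were grouped by their transduction label, 1 pooled library per group. Per the submitters' processing notes, Bowtie2 2.2.3, MACS2 2.1.1.20160309 and build hg19 were used. Their roles, settings and the handling of duplicates are not given in the sources used here, nor is the use of the untagged pool as the control of the peak caller.

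The authors deposited 1 peak list in the narrowPeak layout, with 1 summit per peak. Its deposited fold column was read as the linear ratio of summit pileup to local background. Its deposited −log10 columns were read as −log10 p and −log10 q of the summit, and the lowest q value shows a threshold of 0.1. The deposited score column equals the whole part of 10 times −log10 q in 100% of peaks and was not used further. The other deposited columns hold the start, end and summit position of each peak. Fold and q describe peaks within this list only. Every summit lay inside its peak.

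The depth behind each peak was recovered from the deposited fold and −log10 p by solving fold = (pileup + 1)/(background + 1) together with the Poisson upper tail for p. The pileup came out whole within 0.05 for 99.9997% of peaks, all but 1. The background had a floor of 4.29 reads, taken by 302553 peaks within 0.005, and called the shared background in the report. The 13132 background values above the floor and below 20 reads fell on whole multiples of 0.470 reads, within 0.05 of a step, in 92.5% (92.0 to 92.9) of cases. The 102 values of at least 20 reads were left out of that check. That step is taken here as 1 read of the control library scaled by 0.470, which makes the control 2.13 times as deep as the tagged library. This is an inference from the values, and the control is assumed to be the untagged pool. At the floor the local control coverage is at most 9 such steps, and its exact level is hidden.

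The primary set was the 5000 strongest peaks by −log10 q, with ties broken by fold and then position. It shared 4566 peaks (91.3%) with the 5000 strongest by fold. Peaks named by position were fixed by rule before the data were examined, as the 20 strongest by −log10 q, the 20 strongest by fold, and the strongest of each chromosome, of which the text gives a part. The 2 low peaks of the chromosome 12 interval are named outside that rule and were chosen after their values were seen. Expected shares per chromosome used the span between the first and last peak. Segment ends on chromosomes 3 and 21 came from a maximum-scoring interval search. The pileup ratio of a region was interpolated on the curves of peaks per Mb by pileup, with intervals from 200 bootstrap draws of 1 Mb bins, and is not itself a copy number. Being read off densities, it is not independent of the number of peaks, so the share of taller peaks among those listed was computed as well. For shares in scaled reference pileups, the curve was interpolated between whole reads, with whole reads alone as the alternative. A share has an exact Clopper-Pearson interval. The limit of 25 reads for strong peaks, the limit of 20 reads for a high background, the chromosome 12 interval and the 2 segments were chosen after the data were seen. On peaks simulated with the same formula, the pileup of 100% of 20000 peaks was recovered, which checks the solving step only. In a simulated chromosome with a nearly empty segment, the segment ends were found to within 100 kb. The search for a dense segment, as used on chromosome 21, was not simulated. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

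The alternatives tried were stricter q thresholds, merging of peaks, other numbers of strongest peaks and ranking by fold. The gene annotation at hand is of another build (GRCh38.p14) than the peaks, so none of its coordinates were used. The planned promoter share, genomic context, peaks over ETV6 exons, motifs at summits and tests of 18 gene lists were therefore not analysed here, and 0 gene lists were tested. Gene positions by chromosome band are textbook background.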

Results

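Binding of ETV6, an ETS-family transcription factor that acts mainly as a repressor, was mapped by chromatin immunoprecipitation sequencing in Reh cells. Reh is an established pre-B acute lymphoblastic leukaemia line that carries the t(12;21) translocation joining ETV6 to RUNX1. Cells were transduced with a lentiviral vector for ETV6 carrying an HA epitope tag, and the tagged protein was isolated with anti-HA beads. Cells transduced with untagged ETV6 went through the same anti-HA pulldown as the negative control, per the labels. Each arm was given as 1 pooled library. The tagged pool has 1 peak list in hg19 coordinates, and the untagged pool has 0 lists of its own, so its level could be read here only through the background value recovered at each peak, if that background came from it, which is assumed. No replicate spread could be measured and no test between the libraries was made. Intervals are exact Clopper-Pearson 95% intervals unless stated otherwise, and cover counting error over peaks only. The number of reads per library was not used here. Depth is therefore given as the pileup of reads at each peak summit.

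The question was where tagged ETV6 sat in the genome. The list held 315787 peaks on 25 sequences and covered 35.3 Mb. Most peaks were weak and narrow. The median peak was 99 bp wide, with 5% of peaks below 54 bp and 5% above 213 bp, and had a fold enrichment of 2.84 over background, as the authors' peak caller gave it. The median summit pileup was 14 reads and the lowest was 12. At the background that 95.8% of peaks shared, 4.29 reads, 1 read more or less changed the fold enrichment by 0.189. A pileup of at least 16 reads was reached by 66937 peaks, of at least 20 by 8409, of at least 30 by 1691 and of at least 100 by 121. Of all peaks, 282230 (89.4%, 89.3 to 89.5) had q of at most 0.05, 65346 (20.7%, 20.6 to 20.8) had q of at most 0.01, and 1462 (0.463%, 0.44 to 0.487) had −log10 q of at least 10. Width grew with pileup. Autosomal peaks at the shared background had a median width of 87 bp at 12 to 15 reads (n = 241940), 243 bp at 25 to 39 reads (n = 980) and 373 bp at 60 to 99 reads (n = 139). The 5000 strongest peaks by −log10 q had a median fold enrichment of 4.38, a median width of 236 bp and a median pileup of 24 reads.

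The largest fold enrichments of the list lay in a 139 kb interval of chromosome 12, from 11905360 to 12043992. ETV6 itself maps to 12p13. Whether these peaks overlap exons of ETV6 was not tested, because no hg19 annotation was used here. Cells of both arms carried an ETV6 vector. Reads from vector DNA were not told apart from binding at these sites, so these folds cannot be read as occupancy alone. The interval held 9 peaks, of which 7 had fold enrichments of 33.5 to 469, and these 7 covered 1.16% of its length. The highest peak of the whole list by both fold and q was at chr12:12022335-12022925, with a pileup of 8853 reads over a background of 17.9 reads and a fold enrichment of 469. The peak at chr12:11992051-11992264 had a fold enrichment of 349, that at chr12:12006333-12006516 had 228, and that at chr12:12037358-12037543 had 209. The peak at chr12:11905360-11905534 followed at 132, with lower values of 44.8 at chr12:12043858-12043992 and 33.5 at chr12:12038843-12038968. At 6 of these 7 peaks the background was the shared 4.29 reads. The other 2 peaks of the interval had pileups of 30 reads, at chr12:11951887-11952090, and 15 reads, at chr12:12026754-12026854. No peak was listed in the next 244 kb. Outside the interval the largest fold enrichment was 39.9.

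**Figure D1:**
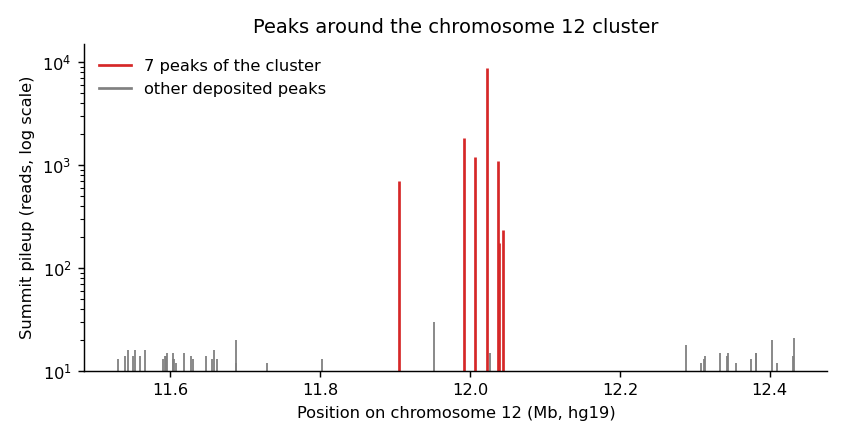
Summit pileup in reads (log scale) of each deposited peak against its position on chromosome 12 in Mb of hg19, with the 7 high peaks of the cluster in red and other peaks in grey. The red peaks run from 176 to 8853 reads.

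Most of the chromosome 12 peaks were narrow beside other tall peaks at the shared background. The 7 high peaks had a median width of 184 bp, against 467.5 bp (range 303 to 1030) for the other 24 peaks of the list at the shared background with a pileup of at least 100 reads. Of the 7, 6 were narrower than all of those 24. The difference in median width had p = 0.00192 in a two-sided exact permutation test over peaks. Of the 7, 6 had pileups of 236 to 8853 reads, above the 210 reads of the highest of the 24, so heights were not matched. Peaks are not replicates, and the comparison was chosen after the peaks were seen to be narrow. Over all 121 peaks with at least 100 reads, the 7 included, the median width was 292 bp. Tall peaks with a raised background varied in width, from 142 bp at chr10:42385167-42385308 (826 reads) to 988 bp at chr1:121484426-121485413 (5489 reads), for instance.

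Away from this cluster, the strongest peaks by fold were scattered over many chromosomes. The highest by fold was at chr5:17282973-17283349, with a fold enrichment of 39.9 and a pileup of 210 reads. On chromosome 19, the peaks at chr19:13266364-13267112, chr19:42384339-42384678 and chr19:54518394-54518732 had fold enrichments of 34.6, 27.4 and 22.5. On chromosome 17, chr17:8982704-8983733 had 33.3, chr17:39723468-39724058 had 27.4 and chr17:45252196-45252575 had 26.7. On chromosome 16, chr16:89682983-89683452 had 30.8 and chr16:1296817-1297409 had 28.6. The remaining peaks among the 20 with the largest fold were chr4:77439458-77439856 at 30.5, chr7:100396631-100397220 at 29.5, chr1:114392674-114393095 at 24.6 and chr7:82587469-82587771 at 23.5. All of these peaks outside the chromosome 12 interval had the shared background of 4.29 reads. Elsewhere, the strongest peak of a chromosome by q lay at chr13:46962402-46962915 with a fold of 22.1, at chr8:38500841-38501271 with 21.9, at chr15:45330180-45330500 with 20.6, at chr3:126009213-126009473 with 18.3 and at chr22:28006868-28007116 with 14, each at the shared background.

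Ranking by q instead of fold brought in peaks at places where the background was also high. Of the 20 strongest peaks by −log10 q, 14 had a background above the shared level and 12 had a background of at least 20 reads. Among the 20 strongest by fold the numbers were 1 and 0, and 7 peaks were in both rankings. The peak at chr7:61968803-61969628 had a pileup of 8697 reads over a background of 2556 reads, a fold of 3.4. That at chr1:121484426-121485413 had 5489 reads over 1595, a fold of 3.44, and that at chr6:58776830-58777807 had 3399 over 850.5, a fold of 3.99. The peak at chr16:46391911-46392128 had a fold of 6.42 and that at chr10:42385167-42385308 had 12.9. The chromosome 1 peak ended directly before a gap of 21.05 Mb without peaks. Another high-background peak, at chr6:58778114-58779359, ended directly before a gap of 3.26 Mb. In the whole list 102 peaks had a background of at least 20 reads, with a median fold of 3.76. Of these, 22 lay on chromosome 16, 16 on the mitochondrial genome, 11 on chromosome 10 and 11 on chromosome 21. The strongest peak by q had such a background on 11 of the 25 sequences and the shared background on 9. Of the 5000 strongest peaks by q, 24.2% (23.1 to 25.5) lay above the shared background, against 15.6% (14.6 to 16.7) of the 5000 strongest by fold and 4.19% of all peaks.

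**Figure D2:**
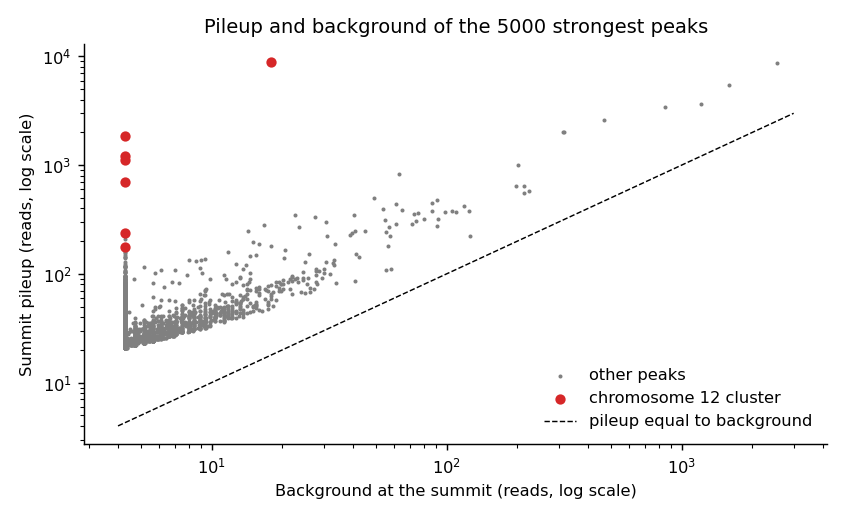
Summit pileup in reads against background in reads (both log scales) for the 5000 strongest peaks by −log10 q, with the 7 high peaks of the chromosome 12 cluster in red and the dashed line where both are equal. Of the red peaks, 6 lie at the shared background of 4.29 reads with pileups from 176 to 1845, where the highest grey peak has 210, and the highest grey peak of all has 8697 reads over a background of 2556.

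Strong peaks fell into dense blocks and isolated sites. A pileup of at least 25 reads, a limit chosen after the pileups were seen, was reached by 2808 peaks. Of these, 1259 (44.8%) lay in 37 bins of 1 Mb with at least 10 such peaks each, and 90.1% of those had a background above the shared level, against 14.7% of the strong peaks elsewhere. Dense bins in the distal part of chromosome 21 differed. At 44 to 45 Mb 3 of 16 strong peaks were above the shared level, and at 45 to 46 Mb 3 of 19. At 46 to 47 Mb the number was 2 of 14. The densest bins were at 190 to 191 Mb of chromosome 4 with 147 strong peaks, 10 to 11 Mb of chromosome 21 with 143, 11 to 12 Mb of chromosome 21 with 123, and 145 to 146 Mb of chromosome 1 with 96. Some dense bins bordered long gaps without peaks. On chromosome 21 a gap of 3.15 Mb began at 11188112, and on chromosome 16 a gap of 11.1 Mb ended at 46386086. The densest bin, on chromosome 4, bordered no gap over 500 kb between peaks. It lay at the end of the listed peaks, however, as the last peak of that chromosome ended at 191033789. What these gaps are was not tested. Outside the 37 dense bins and the chromosome 12 interval, 1315 strong peaks had the shared background. Their median width was 265 bp and their median fold enrichment 6.24. Per Mb of the whole span, from which the dense bins were not taken out, they numbered 1.5 on chromosome 19 (88 peaks), 1.06 on chromosome 22, 0.956 on chromosome 21, 0.826 on chromosome 17 and 0.621 on chromosome 16. They were sparse on chromosome 5 with 0.266 per Mb, chromosome 4 with 0.304 and chromosome X with 0.0659 (10 peaks). With the dense bins kept, chromosome 21 came first with 2.38 per Mb (92 peaks) ahead of chromosome 19 with 1.5.

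Peaks of all strengths were unevenly spread over the chromosomes. The median autosome had 114.9 peaks per Mb of the span between its first and last peak. Chromosome 21 had 338.7 per Mb, chromosome 22 had 206.6 and chromosome 17 had 161.1, while chromosome 4 had 79.5. Chromosome X had 130 peaks, or 0.857 per Mb. Chromosome 21 made up 1.29% of the summed span of the nuclear chromosomes and held 4.15% (4.08 to 4.22) of their peaks. Among the 5000 strongest by q its share of the nuclear peaks was 15.1% (14.1 to 16.1), or 752 peaks. Of these, 493 lay in the distal part of 21q and 244 in the block between 9417103 and 11188026, so the share depended on which peaks were kept. It was 5.7% among the 1000 strongest. Chromosome X held 0.461% (0.293 to 0.692) of the nuclear peaks among the 5000 strongest, from 5.07% of the span. Chromosome Y is counted in these totals and not described separately.

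**Figure D3:**
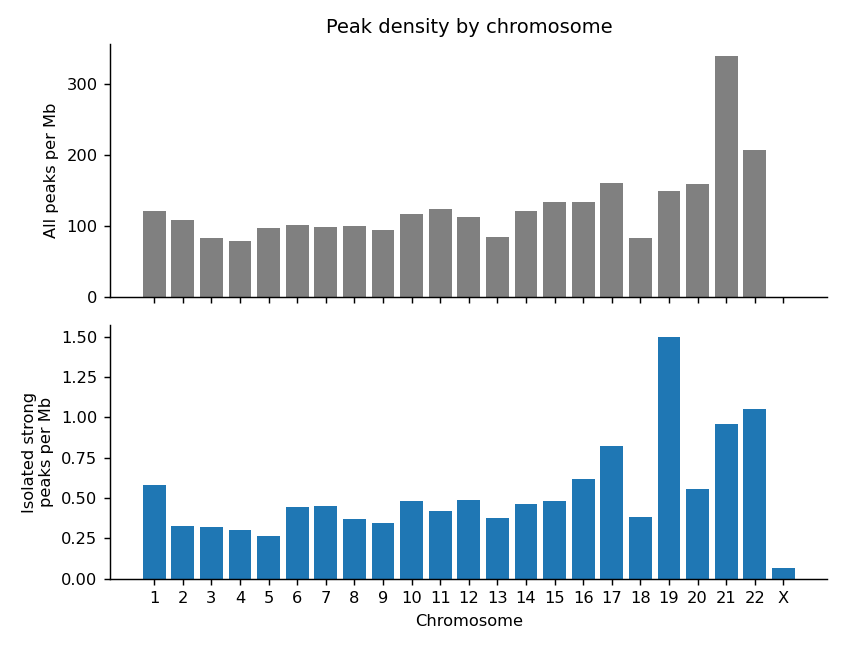
Peaks per Mb of span for chromosomes 1 to 22 and X, with all deposited peaks in the upper panel and isolated strong peaks (at least 25 reads, at the shared background and outside dense bins and the chromosome 12 cluster) in the lower panel. Chromosome 21 stands highest in the upper panel at 338.7 per Mb and chromosome 19 in the lower at 1.5 per Mb.

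Chromosome 21 was dense in 2 places. The block between 9417103 and 11188026 held 837 peaks, of which 290 had at least 25 reads, against 96 such peaks in the distal part of 21q. In the distal part the density rose at a step. From 36320814 to the end of the chromosome, 11.8 Mb held 10664 peaks, or 905.3 per Mb, which was 7.88 times the density of the autosomes other than 3 and 21. RUNX1, the partner of ETV6 in the translocation, maps to 21q22. Its position relative to the step was not checked against an hg19 annotation. The 1 Mb before the step had 204 peaks and the 1 Mb after it 896. The 22 Mb of 21q before the step had 72.9 peaks per Mb. In the distal segment 14.5% (13.8 to 15.2) of peaks had a background above the shared level, against 3.65% (3.58 to 3.72) on the reference autosomes. Among peaks with exactly 15 reads the shares were 14.1% (12.5 to 15.9, 247 of 1746) and 3.73% (3.56 to 3.91, 1784 of 47807).

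**Figure D4:**
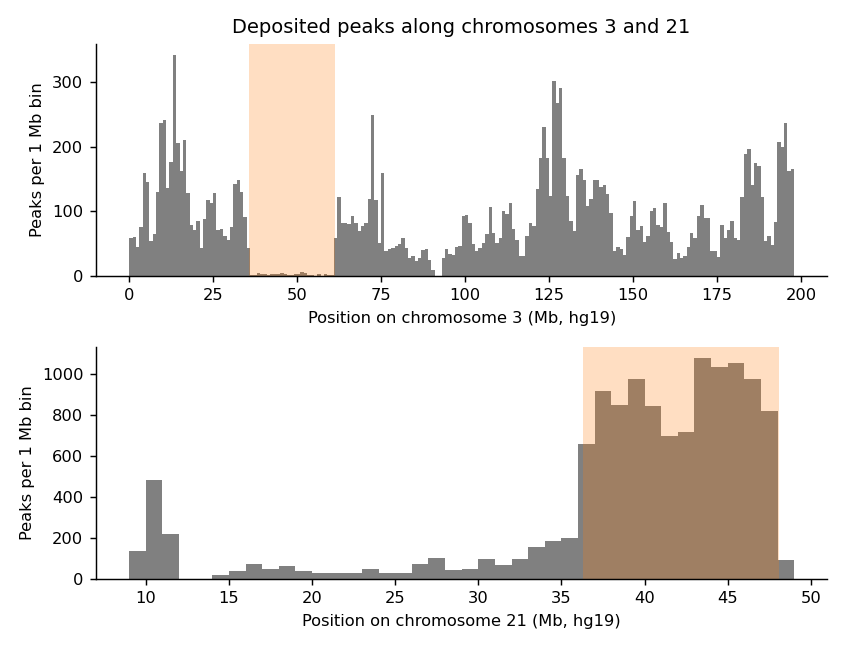
Deposited peaks per 1 Mb bin along chromosome 3 (upper panel) and chromosome 21 (lower panel) against position in Mb of hg19, with the low segment of 3p and the distal segment of 21q shaded. The shaded segments hold 54 and 10664 peaks.

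A segment of the short arm of chromosome 3 was almost empty of peaks. Between 35685879 and 61385878, 25.7 Mb held 54 peaks, or 2.1 per Mb. The 1 Mb before the segment held 63 peaks and the 1 Mb after it 105. The ends of both segments were set by a search for the interval that stood apart most, so their density is not an independent estimate.

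Among the peaks that were listed, heights differed little in the median, which the lower limit of 12 reads holds down. The median pileup was 15 reads in distal 21q, 14 on chromosome X, 13 in the 3p segment and 14 on the autosomes other than 3 and 21. The share of taller peaks differed more. Of the distal 21q peaks with at least 18 reads, 6.87% (5.86 to 8.00) reached 24 reads, against 14.4% on the reference autosomes. The gap depended on the limits, with 16.5% (15 to 18.2) against 20.3% for 18 to 22 reads and 16.3% (14 to 18.9) against 38.4% for 20 to 24 reads. Of the peaks on chromosome X, 20.8% (14.2 to 28.8, 27 of 130) reached 20 reads, as did 11.1% (4.19 to 22.6, 6 of 54) in the 3p segment, against 2.27% on the reference autosomes. The reference autosomes kept their dense bins, such as that at 190 to 191 Mb of chromosome 4 with 147 peaks of at least 25 reads. These shares were not computed without such bins, which add tall peaks to the reference. The curves of density by pileup were also set side by side, as the ratio of the pileup in a region to the pileup at which the reference autosomes had as many peaks per Mb. This ratio is read off peak densities, so it lies above 1 in a dense region and below 1 in a sparse one whatever the cause. In distal 21q it was 1.46 (95% interval 1.40 to 1.52 over 200 bootstrap draws of 1 Mb bins) at 20 reads, 1.42 (1.37 to 1.46) at 24 reads and 1.77 (1.25 to 1.98) at 40 reads. At 12 reads it was 0.475 (0.415 to 0.517) on chromosome X and 0.582 (0.553 to 0.605) in the 3p segment. Chromosomes 17, 19 and 22, rich in genes, had ratios of 1.06, 1.05 and 1.05 at 20 reads and of 1.14, 1.17 and 1.06 at 25 reads, where the upper bounds were 1.23, 1.23 and 1.16. On chromosome 16 the ratio at 25 reads was 1.19 with an upper bound of 1.28.

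**Figure D5:**
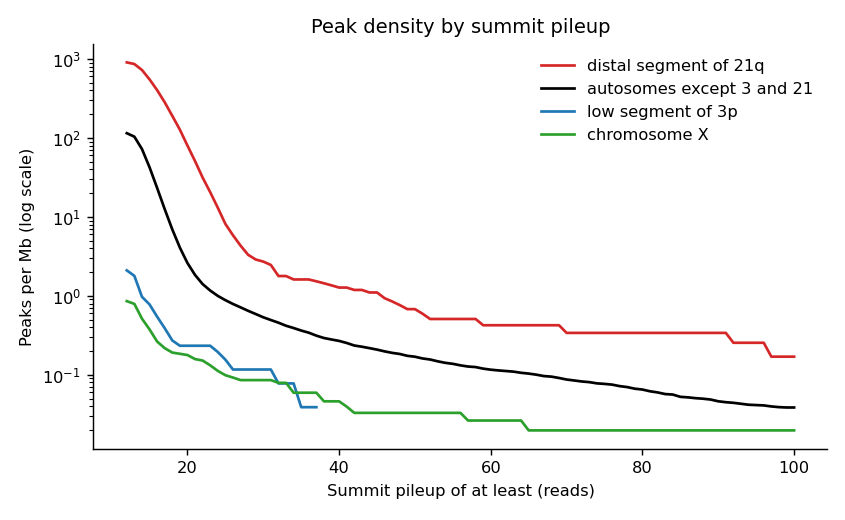
Peaks per Mb (log scale) with a summit pileup of at least the number of reads on the horizontal axis, for distal 21q, chromosome X, the low segment of 3p and the autosomes other than 3 and 21. At 20 reads distal 21q has 80 peaks per Mb and the reference autosomes 2.60.

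Strong peaks lay closer together than weaker peaks drawn in the same number. Among the 1329 autosomal peaks with at least 25 reads at the shared background, leaving out chromosome 21 and the chromosome 12 cluster, the median distance to the nearest such peak was 286 kb, and 12.2% had it within 10 kb. In 100 random draws of as many weaker peaks per chromosome at the shared background, the median was on average 533 kb, with a range over the draws from 468 to 596, and the share within 10 kb was on average 1.63%, with a range from 0.602 to 2.71. Peaks inside the dense bins were kept among the 1329. Among these autosomes chromosome 16 had the largest share inside such bins, with 56 of 71 outside them. On chromosome 19 all 88 lay outside them. How much of the difference the dense bins account for was not measured. The median distance to the nearest peak was 2.09 kb over all peaks and 32.3 kb over the 5000 strongest by q.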

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

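Of 43 alternatives, 21 left a value within its interval, or a count, density or scaled share within 1.5 times, 22 moved it and 0 reversed a direction. Most of these values are levels without a direction, such as counts, widths and shares, so the lack of reversals says little. The limit of 25 reads, the comparisons of background, the dense bins, the scaled shares and the reference chosen for pileup ratios were added after the data were seen. The number of peaks, 315787 as deposited, fell to 65346 at q of at most 0.01, 19675 at 0.001, 4947 at −log10 q of at least 5, 1462 at −log10 q of at least 10 and 2808 with at least 25 reads, by construction, since each keeps fewer peaks. Merging peaks within 1000 bp left 255854. Median width rose from 99 bp to 150 bp at q of at most 0.01 and 236 bp in the 5000 strongest, and median fold from 2.84 to 3.4 and 4.38. The share of the 5000 strongest peaks on chromosome 21, 15.04% with all sequences counted, was 4.15% over all peaks, 5.7% in the 1000 strongest, 12.7% in the 5000 strongest by fold and 14% of peaks with at least 25 reads. The share on X, 0.46%, was 0.0412% over all peaks and 1% in the 1000 strongest. The median distance to the nearest peak went from 32.3 to 2.09 kb over all peaks. The share above the shared background, 24.2%, was 15.6% by fold and 4.19% over all peaks. The causes of the shifts on 21 and X were not tested. The pileup ratio of distal 21q at 24 reads was 1.35 against chromosomes 17, 19 and 22, and isolated strong peaks on chromosome 21 went from 0.956 to 2.38 per Mb with dense bins kept. Alternatives that need an hg19 genome or annotation (promoters, gene lists, motifs, ETV6 exons) were not run, and no replicate could be left out of 1 pooled list. Depth limits what can be said of weak peaks, since a peak of 12 reads and the median of 14 differ by 2 reads.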

Other observations

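Several long stretches held no peak, and 64 gaps between neighbouring peaks were over 500 kb long. Centromeres and other stretches that assemblies leave blank were not separated from the rest. On chromosome 9 no peak was listed from 20662437 to 23129612 (2.47 Mb), while the same length before the gap held 240 peaks and the same length after it 89. On chromosome 5 a gap ran from 126761164 to 128207805 (1.45 Mb), with 62 peaks in the same length before and 86 after. On chromosome 14 a gap of 0.591 Mb ran from 106328504 to 106919323, with 106 peaks before and 51 after. On chromosome 2 a gap ran from 89129440 to 89832566 (0.703 Mb), with 96 peaks before and 93 after.

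The mitochondrial genome, which has no chromatin of the nuclear kind, carried 16 peaks with a median pileup of 342.5 reads over a median background of 70.05 reads, a median fold of 3.80. Weak and strong peaks went together only loosely along the genome. Across 2489 bins of 1 Mb on the autosomes other than 3 and 21, the Spearman correlation between peaks below 20 reads and peaks of at least 25 reads was 0.334, and the Pearson correlation 0.0909. The dense bins were kept, such as that at 190 to 191 Mb of chromosome 4 with 147 strong peaks, so these values do not describe the isolated sites alone. Bins are not independent replicates, and no test was made. The 20% of bins with most weak peaks held 1.41 strong peaks per bin, against 0.575 in the 20% with fewest.

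All tests given for the 3 patterns that follow were chosen after the result was seen, and no biological explanation that contrasts the groups was tested, since the untagged pool has no peak list of its own.

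The first pattern is the chromosome 12 cluster of narrow, very high peaks. More copies of the whole region would lift the sites between the high peaks too, but the highest other peak inside the interval had 30 reads, against 176 to 8853 at the 7 high peaks. An equal amount of the same DNA in the control is argued against by the strongest peak, whose pileup was 495.5 times its background, if that background came from the untagged pool. A candidate explanation that stays open is ETV6 cDNA in the pulled-down DNA, such as copies of the vector. The median width differed by −283.5 bp from that of the 24 other peaks of at least 100 reads at the shared background. That difference restates how the pattern was noticed and decides nothing. Exon positions and the vector sequence were not compared, the control cells carried an ETV6 vector too, and binding of ETV6 at these sites was not excluded.

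The second pattern is the dense distal segment of 21q. A gene-rich region as the whole cause is argued against by chromosomes 17, 19 and 22, where the densest window of the same length held 237.8 peaks per Mb, against 905.3 in the segment. More binding sites of the tagged protein, with nothing else changed, would leave the background alone. That holds if the background came from the untagged pool, which is assumed. Yet 14.1% of distal peaks at 15 reads had a raised background, against 3.73% on the reference autosomes. The control was a pulldown and not a measure of copy number. Its raised background therefore does not tell more copies from other causes shared by both libraries. More DNA copies of the segment may be involved, but copy number was not measured and the heights do not decide it, as 6.87% of distal peaks of at least 18 reads reached 24 reads, below both the 12.2% in reference pileups multiplied by 1.42 (12.1% in whole reads) and the 14.4% in unscaled ones. For other limits the scaled share turned on how whole reads were treated, with 19.2% interpolated and 29.5% in whole reads from 20 to 24 reads (16.3% seen, 38.4% unscaled), and 29.0% and 22.4% from 18 to 22 reads (16.5% seen, 20.3% unscaled). The reference also kept its dense bins of strong peaks, and the shares were not computed without them.

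The third pattern is the scarcity of peaks on X and in the segment of 3p. Evenly fewer sites of unchanged height are argued against, since 20.8% of peaks on X and 11.1% in 3p reached 20 reads, against 2.27% on the reference autosomes. Fewer DNA copies of the 3p segment stay open as a cause of its heights. Reference pileups multiplied by 0.582 give 18.1% at 20 reads (19.8% in whole reads), inside the interval of 4.19 to 22.6. That factor was read off the density of these same peaks at 12 reads, and such a ratio lies below 1 in any sparse region. Only 6 peaks reached 20 reads, so the match is weak evidence. For X fewer copies stay open too. Reference pileups multiplied by 0.475, a factor obtained in the same way, give 27.3% at 20 reads, inside the interval of 14.2 to 28.8. At 16 reads they give 46.6%, where 30.8% (23.0 to 39.5) was seen. Closed chromatin or a loss of weak sites in these regions was not tested and stays open.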
